A study of Mus musculus with 12 samples.

How the data were processed

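RNA of the mouse podocyte line MPC5 was measured on 6 arrays, 3 from cells given a control siRNA and 3 from cells given an siRNA against METTL3, all held for 24 h in 30 mmol/L glucose. Per the labels, each array carried 2 RNA fractions of the same culture, the immunoprecipitated RNA (IP) in Cy5 and the supernatant RNA (Sup) in Cy3, so that the 6 arrays give 12 samples. The labels call the replicates biological. The labels do not name the antibody; METTL3 is the catalytic subunit of the m6A writer complex and the kit maker sells this array format for m6A, so the IP fraction is read here as m6A-enriched RNA. Dyes were not swapped, which leaves a probe's dye bias in its ratio but not in the difference between groups.

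Per the file headers, the authors' spot intensity values came from Agilent Feature Extraction 11.0.1.1, whose processed signal is background-subtracted and dye-normalized within the array by a linear factor and a lowess curve. That step sets the overall level of Cy5 against Cy3, so a shift of the whole IP-to-Sup ratio is largely removed from the processed signals. The authors' deposited value table holds log2 values of 27920 probes. Each of its columns differed from log2 of the processed signal, averaged over a probe's spots, by a constant for that array and channel, and the largest departure from it was 5.00e-09. The medians of its IP columns were 1.45, 1.21 and 1.28 for control replicates 1 to 3 and 1.52, 1.36 and 1.38 for knockdown replicates 1 to 3. Those of its Sup columns were 1.54, 1.46 and 1.64, then 1.67, 1.77 and 1.56. Its scale and direction are therefore known, and how its constants were set stays unknown.

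The starting point was the processed signal, with spots marked as outliers left out and the spots of a probe averaged. Control-type probes stayed out of the tests, which left 60691 transcript probes. The IP-to-Sup ratio is log2(IP/Sup) centred on each array's median over tested probes. IP RNA is log2 of Cy5, and total RNA log2 of Cy5 plus Cy3, each less the array's 75th percentile. A probe was tested when well above background on at least 3 of the 6 arrays, in both channels for the ratio, in Cy5 for IP RNA and in either channel for total RNA. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, files were read with version 1.17.8 of data.table, and p-values were adjusted by Benjamini-Hochberg at 0.05. Values with 1 number per array were compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 arrays against 3.

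The number of arrays limits the precision. The share of transcript probes well above background in Cy5 was 45.4%, 37.6% and 42.5% on control arrays 1 to 3 and 51.1%, 49.9% and 41.9% on knockdown arrays 1 to 3. In Cy3 it was 79.3%, 76.1% and 80.9%, then 81.2%, 75.2% and 80.1%. No transcript probe was saturated. Control replicate 2 was scanned apart from the other 5 arrays, so a term for the scan takes out that array and gives nearly the fit without it.

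Gene names came only from accessions in the files, matched without versions to RefSeq transcripts of the mouse assembly GRCm38.p6. Of 50 Agilent catalogue probes, each printed in 10 spots, 45 matched a symbol and 5 did not. The remaining transcript probes carry serial IDs in 3 prefix families, EP3A (48057 probes), EP3B (8497) and SM (4087), which the files do not pair with genes. The file headers name the mouse build mm9 for the probe layout, so no coordinates are given. The RNA class of each family is not given in the sources used here.

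Before the data were examined, the tests, the alternatives, 27 gene lists and the rule for named genes were fixed. That rule takes the 12 largest rises and 12 largest falls that pass the adjusted threshold, with groups that do not overlap and signal well above background on all 6 arrays. Where fewer than 5 pass in a direction, it adds the probes with the smallest unadjusted p up to 5, as values only. Here these were taken only from named probes well above background on all 6 arrays, which left out dimmer ones such as Taf1a. It also takes list members, Mettl3 and Timp2. The rule foresaw at most 2 probe IDs per direction if no genes were named. Here that was applied to the probes without a gene. The IDs given are those with the smallest p among probes well above background on all 6 arrays, in both channels for the ratio and total RNA and in Cy5 for IP RNA. Lists with fewer than 5 tested members get values only, so no set test was run.

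Whether equal replicate numbers pair the arrays was checked by correlating their deviations from the group means. For total RNA the correlations of the 3 pairs ran from 0.180 to 0.345 and for Sup RNA from 0.323 to 0.582. All were over 0.1, the mark set for pairing. For the ratio they ran from -0.00313 to 0.0929 and for IP RNA from 0.0692 to 0.303. A pair of unequal number, control 3 with knockdown 1, reached 0.191 for total RNA, above the lowest pair of equal number. For Sup RNA it reached 0.291, just under that lowest pair. Pairing by number is read from the data alone and is not settled by these values. The labels give a number and a name for each array, and state no pairing. The names of replicate 3 have another form in both groups, for a reason the labels do not give.

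The fit was tested on simulated data with the real probe means and variances drawn from the prior that limma fitted, changing 200 probes. At a log2 change of 1 it recovered 0 of 200 in each of the 3 comparisons. At a log2 change of 2 it recovered 89.5% for the ratio (27129 probes), 59.5% for IP RNA (27184 probes) and 82.0% for total RNA (47650 probes). At a log2 change of 3 it recovered 99.0%, 86.5% and 96.5%. The simulated noise was independent between probes and alike on all arrays, so these shares are not the power in the real data. They also hold only for 200 changed probes. Alternatives covered background correction, filters, scaling, variance model, the authors' value table, the replicate block, the threshold and each array left out. Array weights, the authors' constants on all tested probes, the replicate block for Sup RNA, spike-in scaling for total and Sup RNA and a term for the scan were added after seeing the data.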

Results

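The arrays measured IP and Sup RNA of MPC5 cells, a conditionally immortalised mouse podocyte line, in high glucose with METTL3 knocked down or not. The design text names knockdown against control as the comparison. There were 3 control and 3 knockdown arrays, each giving an IP and a Sup sample. Values are log2 means ± SD over 3 arrays, and differences are knockdown minus control. No probe named Mettl3 or Timp2 was among the 45 named probes, so the knockdown itself was not analysed here. Each statement below on the knockdown arrays rests on their labels.

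The IP-to-Sup ratio, the measure of methylation level, was lower for Chgb and Lhfp and higher for Pex11a in the knockdown, none past the test. Chgb, which encodes the secretory granule protein chromogranin B, went from 0.32 ± 0.48 to -0.21 ± 0.26 (SD, n = 3). Its difference of -0.53 had a 95% interval from -1.15 to 0.10 (limma, adjusted p = 1). Lhfp went from -0.14 ± 0.22 to -0.49 ± 0.13 (SD, n = 3), with each knockdown array below each control array and a difference of -0.34. Pex11a, a peroxisome proliferation factor, went from 0.51 ± 0.42 to 0.84 ± 0.37 (SD, n = 3), a difference of 0.33.

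Anxa8, Actb and Cav2 also had lower ratios, with differences of -0.21, -0.20 and -0.21. Gpi1, Nup50, Duox1 and Uhrf1bp1l had higher ratios, with differences of 0.20, 0.12, 0.12 and 0.12; with spike-in centring Nup50, Duox1 and Uhrf1bp1l changed sign, as did Duox1 with normexp and with quantile normalization of each channel. Quantile normalization of each channel gave -0.51 for Anxa8, -0.53 for Actb, 0.085 for Pex11a and 0.010 for Gpi1, and normexp gave 0.12 for Pex11a, -0.55 for Anxa8, -0.42 for Actb, -0.17 for Lhfp and -0.080 for Cav2. Several of these differences depended on 1 array. Without control replicate 1 that of Chgb was -0.25, of Lhfp -0.22, of Anxa8 -0.055, of Actb -0.094 and of Cav2 -0.00095. Without control replicate 2 that of Chgb was -0.69, of Lhfp -0.44, of Cav2 -0.36, of Gpi1 -0.044, of Pex11a 0.19 and of Uhrf1bp1l 0.00070, and without knockdown replicate 3 that of Duox1 was 0.031. That of Pex11a was 0.57 without control replicate 3 and 0.54 without knockdown replicate 2. Of the 32 named genes tested, 18 had a higher and 14 a lower mean ratio, and none reached an unadjusted p under 0.05. Under other settings Chgb did, at 0.0438 with the replicate block, 0.0392 without control replicate 2 and 0.0321 with array weights, chosen after seeing the data, as did Anxa8 at 0.0377 with normexp background correction. In 2 of the 32, or 6.25%, the groups did not overlap, where chance gives 10%. Over the named genes, the median SD was 0.20 between control arrays, 0.14 between knockdown arrays and 0.12 between spots of an array.

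Across 27129 probes, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 807 probes, 442 higher and 365 lower, or 2.97% where chance gives 5%. The split moved with the processing: with spike-in centring 99 were higher and 709 lower, with no centring 606 and 262, with normexp 413 and 89, and with loess 392 and 504. Without control replicate 1 the unadjusted count was 1606, without control replicate 3 it was 1223 and without knockdown replicate 3 it was 490. The median half-width of the unadjusted 95% interval was 0.53. Among unnamed probes well above background in both channels on all 6 arrays, those with the smallest p were ASMM10EP3A100174627 and ASMM10EP3A115730424, with differences of 1.09 and 0.72, and ASMM10EP3A128961412 and ASMM10EP3A105955766, with -0.72 and -0.97; none passed.

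**Figure D1:**
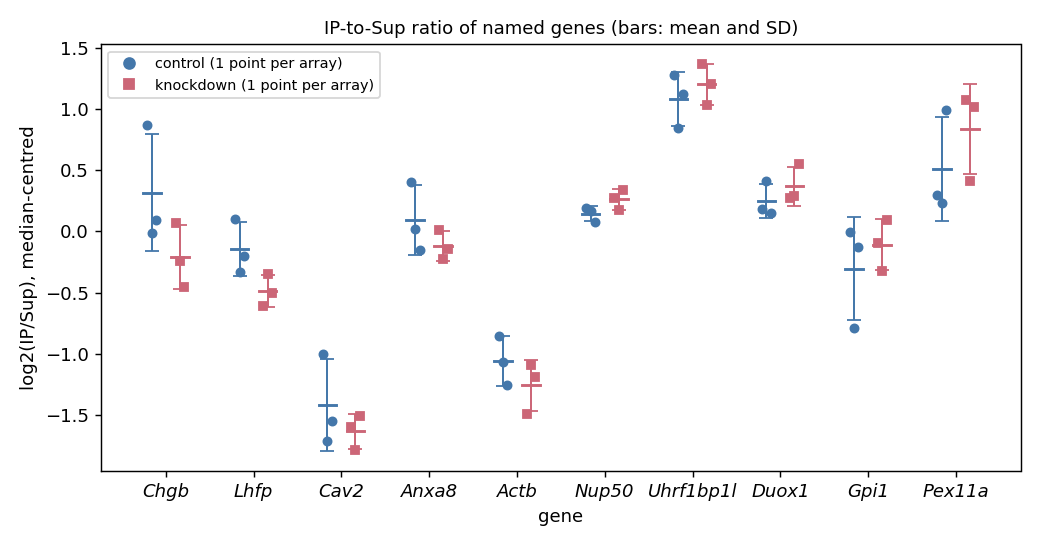
Median-centred log2(IP/Sup) of the 10 genes named by the rule, with genes on the x axis, 1 point per array, and bars for the mean and SD of 3 control (circles) and 3 knockdown (squares) arrays. The groups overlap in each gene except Lhfp, where the means are -0.14 and -0.49; none passed the test.

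IP RNA, the amount in the immunoprecipitated fraction, was lower in the knockdown for Anxa8, E2f1 and Actb, with groups that did not overlap, but none passed the adjusted threshold. Anxa8, an annexin that binds membranes in the presence of calcium, went from 5.45 ± 0.30 to 4.23 ± 0.78 (SD, n = 3). E2f1, a transcription factor of the G1 to S transition, went from -0.32 ± 0.11 to -0.93 ± 0.04 (SD, n = 3). Actb, cytoplasmic beta-actin, went from 5.65 ± 0.23 to 4.99 ± 0.12 (SD, n = 3). Their differences were -1.22, -0.61 and -0.65, with unadjusted limma p-values of 0.0163, 0.0210 and 0.0224 and an adjusted p of 0.788 each. With the authors' constants, an alternative chosen after seeing the data, the differences were -0.98, -0.37 and -0.42. With spike-in scaling they were -0.86, -0.25 and -0.30, and in both settings the unadjusted p of E2f1 and Actb was over 0.05.

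Olfr166 and Chgb followed with differences of -1.03 and -0.51; without control replicate 2 these were -0.40 and -0.79. That of Chgb was -0.33 without control replicate 1 and -0.15 with spike-in scaling. Among genes well above background on all 6 arrays, Carhsp1, Acaa2 and Nup50 were higher, with differences of 0.14, 0.06 and 0.05. Without control replicate 3 those of Acaa2 and Nup50 were -0.0045 and -0.13, and without knockdown replicate 2 that of Carhsp1 was 0.010. The highest values over 18 alternatives were 0.42 for Acaa2, 0.41 for Nup50 and 0.49 for Carhsp1. Of 32 named genes, 26 were lower and 6 higher, and relative to the median change of all probes, -0.15, these became 20 and 12. Groups did not overlap in 7 of the 32, or 21.9%, where chance gives 10%. That median shift can raise the share, so it does not set the named genes apart. Adjusted over the named genes alone, the smallest p was 0.239.

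Across 27184 probes, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1111, where chance gives 1359, with 198 higher and 913 lower. That direction depended on scaling: with the authors' deposited values 604 were higher and 147 lower, and with spike-in scaling 625 and 59. Without control replicate 2 there was 1 adjusted call, and the unadjusted count was 1782 without control replicate 1, 424 without knockdown replicate 1 and 643 without knockdown replicate 2. Among unnamed probes well above background in Cy5 on all 6 arrays, those with the smallest p were ASMM10EP3A100125164 and ASMM10EP3B106296052, with differences of 1.32 and 0.85, and ASMM10EP3A114217351 and ASMM10EP3A111451810, with -1.53 and -1.10; none passed.

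Total RNA, the sum of both dye-normalized fractions, was lower in the knockdown for the same 3 genes, E2f1, Anxa8 and Actb. None passed the adjusted threshold. The sum holds the IP signal, so it is not a second observation of these genes. Dye normalization brings the channels to a like level, so the fractions are not weighted by their amounts. E2f1 went from -0.48 ± 0.16 to -1.08 ± 0.08 (SD, n = 3), a difference of -0.60 with a 95% interval from -1.02 to -0.18. Anxa8 went from 5.36 ± 0.40 to 4.21 ± 0.80 (SD, n = 3), with knockdown replicate 3 at 5.13 inside the control range. Actb went from 6.21 ± 0.39 to 5.66 ± 0.11 (SD, n = 3). Their unadjusted limma p-values were 0.0109, 0.0188 and 0.0454, with an adjusted p of 0.807 each. With the authors' constants in place of the percentile, an alternative chosen after seeing the data, the differences were -0.35, -0.90 and -0.31, and the unadjusted p of E2f1 and Actb was over 0.05. Over 19 alternatives the difference of E2f1 lay between -0.66 and -0.27, that of Anxa8 between -1.61 and -0.88 and that of Actb between -0.77 and -0.31. With an array left out, the unadjusted p of Actb ranged from 0.00931 to 0.152, that of Anxa8 from 0.000729 to 0.0710 and that of E2f1 from 0.0200 to 0.0309. In Sup RNA alone the differences of E2f1, Anxa8 and Actb were -0.49, -0.95 and -0.40. Their unadjusted limma p-values there were 0.0232, 0.0555 and 0.158, and the groups overlapped for Anxa8 and Actb.

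Olfr166 and H2-M2, an olfactory receptor and a class I histocompatibility gene, had differences of -1.01 and -0.43, while Carhsp1 and Acaa2 were at 0.10 and 0.01. Without control replicate 2 those of Olfr166 and H2-M2 were -0.39 and -0.23, and without knockdown replicate 2 those of Carhsp1 and Acaa2 were -0.029 and -0.039. Of 41 named genes, 36 were lower and 5 higher, and relative to the median change of all probes, -0.15, these became 29 and 12. Groups did not overlap in 6 of the 41, or 14.6%, where chance gives 10%. Of the 6, Dnajc11, Atg3 and Cpt1a were not well above background in both channels on any array. The shift of the median of all probes can raise this share, so it does not set the named genes apart. The control spots for Gapdh and Pgk1, both glycolytic enzymes, were lower as well. Gapdh probe 3 went from 6.02 ± 0.39 to 5.56 ± 0.12 and Pgk1 probe 3 from 7.74 ± 0.59 to 7.12 ± 0.20 (SD, n = 3; exact two-sided permutation p = 0.1 each, the smallest possible). Gapdh probe 5 went from 6.06 ± 0.61 to 5.66 ± 0.18 (SD, n = 3; exact two-sided permutation p = 0.6) and Pgk1 probe 5 from 1.48 ± 0.13 to 1.02 ± 0.36 (SD, n = 3; exact two-sided permutation p = 0.2). With the authors' constants the differences of Gapdh were -0.22 for probe 3 and -0.15 for probe 5, and those of Pgk1 -0.37 and -0.21, with exact permutation p-values of 0.3, 0.8, 0.3 and 0.5. The differences of Gapdh, -0.47 and -0.40, were -0.25 and -0.048 without control replicate 2, and those of Pgk1, -0.62 and -0.46, were -0.28 and -0.40.

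Across 47650 probes, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 2076, where chance gives 2382, with 149 higher and 1927 lower. With the replicate number as a block the adjusted count stayed 0 and the unadjusted count was 4175. Normexp gave 7061 unadjusted calls, 53 higher and 7008 lower, and quantile normalization 3406, 352 higher and 3054 lower. The authors' deposited values gave 518 higher and 160 lower, and spike-in scaling, chosen after seeing the data, 42 higher and 2804 lower with 1 adjusted call. Without control replicate 2 there was 1 adjusted call, and the unadjusted count was 1164 without knockdown replicate 1 and 1348 without knockdown replicate 2. For Sup RNA alone, 48522 probes gave 0 adjusted calls and 585 at an unadjusted p under 0.05, where chance gives 2426. Of the 585, 80 were higher and 505 lower. With the replicate block, for Sup RNA chosen after seeing the data, the adjusted count stayed 0 and the unadjusted count was 3498, 246 higher and 3252 lower. Spike-in scaling gave 17 adjusted and 2577 unadjusted calls for Sup RNA, but with it limma gave single probes' own variance no weight, and in 9 of the 17 the groups overlapped. Among unnamed probes well above background in both channels on all 6 arrays, those with the smallest p were ASMM10EP3A100125164 and ASMM10EP3B106296052, with differences of 0.98 and 0.63, and ASMM10EP3A114217351 and ASMM10EP3A108331307, with -1.61 and -1.05; none passed.

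**Figure D2:**
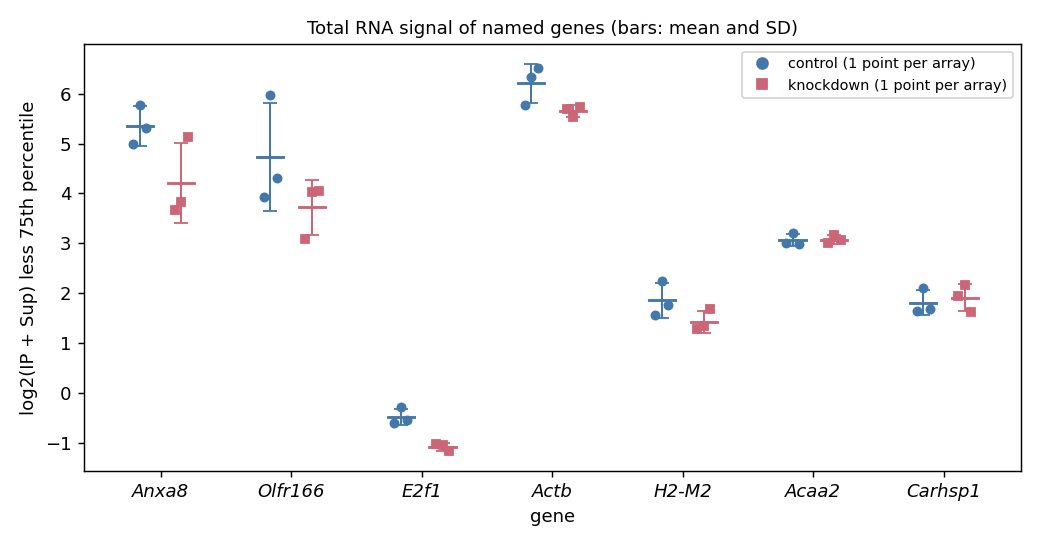
Log2(IP + Sup) less the 75th percentile of the array for the 7 genes named by the rule, with genes on the x axis, 1 point per array, and bars for the mean and SD of 3 control (circles) and 3 knockdown (squares) arrays. E2f1 and Actb have groups that do not overlap, with E2f1 means of -0.48 and -1.08; none passed the adjusted threshold.

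Gene lists could be followed only through single members. Of 556 listed genes, 5 had a named transcript probe, in 5 of the 27 lists, and 0 lists had 5 tested members. The cell cycle list was represented by E2f1 and the actin cytoskeleton list by Actb, with the values above. Gpi1, of the glycolysis list, went from 6.78 ± 0.28 to 6.51 ± 0.16 in total RNA (SD, n = 3), a difference of -0.27 that was -0.11 without control replicate 2 and -0.031 with the authors' constants. Gsdmd, the pore-forming protein of pyroptosis, went from 4.15 ± 0.69 to 3.75 ± 0.28 (SD, n = 3), a difference of -0.40 that was -0.010 without control replicate 2. Atg3, of the autophagy list, was well above background in Sup on 6 arrays, but in both channels not on any array. Its total RNA went from -2.96 ± 0.15 to -3.26 ± 0.16 (SD, n = 3), a difference of -0.30 (limma, unadjusted p = 0.157, adjusted p = 0.807). Of the m6A writers, erasers and readers, the podocyte markers and the markers of other cell types, none had a named probe.

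The families of probe IDs, the nearest equivalent to RNA classes here, were compared by their median ratio, with 3 arrays against 3, where no exact p under 0.1 is possible. Less the EP3A median, the median ratio of EP3B was 0.07 ± 0.00 in control and 0.08 ± 0.01 in knockdown arrays (SD, n = 3; exact two-sided permutation p = 0.4). That of SM was 0.16 ± 0.05 and 0.21 ± 0.08 (SD, n = 3; exact two-sided permutation p = 0.6). In each family 0 probes passed the adjusted threshold for the ratio or for total RNA. At an unadjusted p under 0.05 the ratio gave 643 of 22127 EP3A probes, 97 of 3082 EP3B probes and 67 of 1887 SM probes.

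The overall IP-to-Sup ratio before dye normalization had a median of -1.37 ± 0.21 on control and -1.04 ± 0.72 on knockdown arrays (SD, n = 3; exact two-sided permutation p = 0.6). The array medians were -1.18, -1.32 and -1.60 for control replicates 1 to 3 and -1.03, -0.32 and -1.76 for knockdown replicates 1 to 3. Without knockdown replicate 2 the difference of 0.33 became -0.03. The level of a whole array is set by dye and amplification as well as by RNA. Array medians therefore do not decide whether methylation changed as a whole. The spike-in probes used next are known as such only by their names. Less the median of 17 spike-in probes, the medians were 0.12 ± 0.24 and 0.14 ± 0.11 (SD, n = 3; exact two-sided permutation p = 1).

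Changes in ratio and in total RNA correlated across 27129 probes with Pearson's r = 0.474 and Spearman's rho = 0.510, beside an r of 0.354 in 20 simulated sets without group differences, since both measures share the same channels. Over the other splits of the 6 arrays r ranged from 0.127 to 0.524, so a value as high also arose without parting the groups. Their covariance was 0.0404 beside 0.0331 in the simulation. Probes are not independent replicates. With Sup RNA in place of total RNA, r was 0.0320 beside -0.145. No probe passed both adjusted thresholds; at an unadjusted p under 0.05, 100 were lower in both and 27 higher in both, an overlap that the shared channels raise by themselves.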

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

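No result met a criterion for a closer look. Groups of 3 arrays are too small for the check on single outlying samples, and the design holds 1 contrast, so effects could not be compared between settings. Of 43 control-type probes well above background in both channels on all 6 arrays, 0 had each knockdown array above each control array in total signal and 9 had each below, where chance gives 10% for both sides together. That is not a test of the 43. Some lacked a value on a control array and could not be scored. Of the 9, 4 target Gapdh or Pgk1, so the probes are not independent, and the median change of all tested probes was itself -0.15.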

How the results depend on the processing

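Each of the 3 comparisons had 0 probes at an adjusted p under 0.05, and most alternatives left it so; array weights, the authors' constants, a scan term, spike-in scaling of total and Sup RNA and the block for Sup RNA were chosen after seeing the data. Without control replicate 2, 1 probe passed for IP RNA and 1 for total RNA, so that leaving out an array gave 0 to 1. With array weights 2 passed for IP RNA and 1 for total RNA, with a scan term 1 and 1, and with spike-in scaling 1 for total RNA. For Sup RNA spike-in scaling gave 17, and 25 with the replicate block. With an array left out it gave 0 to 16, 0 without control replicate 3. In the fit that gave 17, limma's prior degrees of freedom were infinite. The threshold of an unadjusted p under 0.05 with a fold of at least 1.5 gave 510 probes for the ratio, 980 for IP RNA and 1278 for total RNA. The cause was not tested. Unadjusted counts moved more. For the ratio the count of 807 ranged from 484 to 2797 over settings and from 490 to 1606 with an array left out. The filter changed the number tested, with 484 of 19671 probes and 2797 of 59752. For IP RNA the count of 1111 ranged from 684 to 3756 and from 424 to 1782. For total RNA the count of 2076 ranged from 678 to 7061 and from 1164 to 2902. The 678 came from the 27865 tested probes of the authors' value table. Sup RNA in place of total RNA gave 585. The replicate block gave 888, 1937 and 4175 unadjusted and 0 adjusted calls in each, and for Sup RNA 3498 in place of 585, also with 0 adjusted. The family difference of EP3B, 0.01, became -0.0026 on probes above background on all 6 arrays and -0.0022 with loess, and without single arrays it lay between 0.0016 and 0.014. That of SM lay between -0.0032 and 0.079 without single arrays. The global ratio difference lay between -0.028 and 0.69 without single arrays. The correlation of ratio and total RNA changes was 0.0320 with Sup RNA alone and 0.391 to 0.520 without single arrays. No saturated probe existed, so that filter removed nothing. Gene list alternatives were not run, since no list had enough named members, nor were Mettl3's, which had no named probe, nor the planned scan block, set for scans of more than 1 array. Dim Cy5 signal limits the ratio, with 37.6% to 51.1% of probes well above background.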

Other observations

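A probe without a gene name, ASMM10EP3B101974235, chosen after its values were seen, had the smallest p for IP, total and Sup RNA without the replicate block; with it, its p ranked 2 for Sup RNA. Its Sup RNA went from -0.82 ± 0.18 to -3.01 ± 0.30 and its total RNA from 1.41 ± 0.88 to -1.95 ± 0.15 (SD, n = 3), lower on 3 of 3 knockdown arrays. The limma adjusted p was 0.324 for Sup RNA and 0.807 for total RNA, and 0.474 and 0.562 with the replicate block. Without control replicate 2 it was the 1 probe past the adjusted threshold for total RNA and for IP RNA, and with spike-in scaling the 1 for total RNA. It was well above background on 6 arrays in Sup and on 5 in IP. ASMM10EP3A115218918, likewise chosen after its values were seen, had Sup RNA of -1.96 ± 0.04 in control and -1.13 ± 0.18 in knockdown arrays (SD, n = 3), and passed the adjusted threshold for IP RNA with array weights. In IP it was well above background on 3 of the 6 arrays, with control values of -3.60, -2.41 and -3.67, so that call rests on control signals near background.

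The tests on control replicate 2, on the direction of total RNA and on other splits were chosen after the results were seen. The test on the most enriched probes was not in the first plan. It was set after the main results were seen, but before its own values were.

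Control replicate 2 deviated most from the probe means, with an SD of 0.467 for total RNA where the other arrays lay between 0.269 and 0.324. Noise of single spots was argued against: over 27 named probes of 10 spots its SD was 1.99 times the highest of the others, with a 95% bootstrap interval from 1.18 to 2.17. A different signal distribution may account for the Sup channel, where quantile normalization brought its SD to 0.285 beside 0.291 for the highest other array. It left the IP channel at 0.570 beside 0.401, so the distribution is not the whole account there. The scan cannot be told apart from the array, since that scan held 1 array, and no biological explanation was tested.

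Of the total RNA calls at an unadjusted p under 0.05, 92.8% were lower in the knockdown. Splits that mix the groups were one-sided as well, with up to 84.1% of their total RNA calls in one direction. For Sup RNA the highest such share was 85.6%, beside 86.3% for knockdown against control. Control replicate 2 alone was argued against, since 87.1% were lower without it. With the authors' constants on the same probes the share was 21.5% and the median change of all probes 0.09 in place of -0.15. New constants move all probes of an array nearly alike, so the share had to follow the median, and this does not decide whether the scaling is the cause. With spike-in scaling 98.5% were lower for total RNA, but for IP RNA 8.63%, and the spike-in level itself varied between control arrays, with an SD of 0.38 for total RNA, so a true loss of RNA in the knockdown stays open.

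A hypothesis was that RNAs most enriched in IP lose more of their ratio when METTL3 is knocked down. Among the tenth of probes with the highest mean ratio over all 6 arrays, 1780 probes, the array medians were 0.95 ± 0.15 in control and 1.01 ± 0.14 in knockdown arrays (SD, n = 3; exact two-sided permutation p = 0.5). The difference of 0.066 was opposite to the hypothesis and smaller than the spread within groups. By replicate number 1 to 3, the medians were 1.0527, 0.7716 and 1.0197 in control and 1.0956, 0.8478 and 1.0983 in knockdown arrays. Each knockdown array thus lay above the control array of its number, also opposite to the hypothesis. The sign of the difference between group means rested on control replicate 2, at 0.7716. The other control medians, 1.0527 and 1.0197, were both above the knockdown mean of 1.01. Pairing by number is not settled, and for the ratio its correlations stayed under the mark of 0.1. The test therefore did not decide the hypothesis.

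With 10 splits of 6 arrays no share under 0.05 can be reached. At an unadjusted p under 0.05, knockdown against control gave 807 probes for the ratio and the highest other split 1916, with 10 of 10 splits as large. For IP RNA these were 1111 and 1865, with 5 splits as large, and for total RNA 2076 and 3311, with 5. For Sup RNA they were 585 and 5876, with 9; that highest split set control replicates 1 and 2 and knockdown replicate 2 against the rest, which points to a structure of the arrays apart from the knockdown. If replicate numbers pair the arrays for total and Sup RNA, which is not settled, 4 of the 10 splits part all 3 pairs. The real split is among them, and the others part 1. Among these 4 the highest other count was 1402 beside 2076 for total RNA and 671 beside 585 for Sup RNA. With the replicate block it was 2304 beside 4175 and 2069 beside 3498, and 4 splits are too few for a share under 0.05. The highest splits of all, 3311 for total and 5876 for Sup RNA, each parted 1 pair and kept the other pairs together. Splits that part 1 pair also gave counts as low as 722 for total RNA and 772 for Sup RNA.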
